A study of Homo sapiens with 16 samples.

How the data were processed

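RNA-seq was run on 14 libraries of SK-N-BE2 neuroblastoma cells, and a TEAD4 ChIP-seq peak list came from 1 library of the same line. The first RNA-seq set held 9 libraries, with 3 given control hairpins, 3 labelled MYCN KD and 3 labelled TEAD4 KD. The second set held 5 libraries, with 3 given empty vector and 2 labelled WWTR1 KD. Groups were taken from the sample titles. For the first set the titles and the treatment protocols disagreed. The protocol of the libraries titled MYCN KD names 2 hairpins against TEAD4, and the protocol of those titled TEAD4 KD names 2 hairpins against MYCN. The treatment tags of both groups follow the titles. The libraries titled WWTR1 KD carry a treatment tag that names MYCN, while their protocol names WWTR1. All groups are therefore called by their titles as "labelled". The sets differed in growth medium, control vector, sequencer and processing, so no test was made across them. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

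The deposited RNA-seq values are log2 expression values per gene symbol, made by the authors from reads aligned to hg19. Per the submitters' processing notes, which give no roles, TopHat, limma, edgeR, Bowtie 1.1.1 and MACS2 belong to the first set and the ChIP, and bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3, limma and edgeR to the second. The lowest deposited log2 value of each library corresponds to 0 reads plus 0.5, and from it 100% of the values gave whole reads within a tolerance of 0.01 reads, so the unit is log2 CPM, from reads plus 0.5 over an effective library size. The effective size was between 0.9726 and 1.0222 times the recovered total. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical copies. The deposited peak list gives for each peak an interval in hg19, a fold enrichment and lists of overlapping, proximal and closest RefSeq transcripts, per the file headers. The fold enrichment is the authors' ratio and was used only to describe, rank and filter peaks. The scale of its FDR column is not stated, and that column was not used. The input library of the ChIP was not analysed here. The distance behind the word proximal is not given in the sources used here.

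Before the data were examined, the comparisons, 18 gene lists, the alternatives and the rule for named genes were fixed. That plan assumed read counts and a count model. As the values turned out to be log2 values, limma 3.58.1 (R 4.3.3) was used instead, with its moderated test and an intensity trend on the deposited values. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A gene was tested when it had at least 10 reads in a library of median size, in as many libraries as the smallest group, and at least 15 reads in total. The 9 libraries of the first set shared a fit, and the 5 of the second set another. Fold changes are on the scale of log2 with 0.5 reads added, which understates changes of low genes. The named genes are the 3 targets, the 5 highest and 5 lowest fold changes per comparison with a control (3 and 3 between the knockdowns) among called genes with a mean log2 CPM of at least 3 and no overlap between groups, and the 2 members of each list with the smallest p among those called. Some genes that this rule names are not reported here. Other genes named were chosen after their values were seen.

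Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of at least 5 tested members in each comparison, and again with an estimated correlation. With an estimated correlation camera also takes its degrees of freedom from the few libraries of the fit. That alone raises its p-values, so a call lost there need not come from correlation between genes. The lists cover mitosis, DNA replication, ribosome biogenesis, nucleotide and one-carbon synthesis, MYC family targets, YAP/TAZ-TEAD targets, Hippo pathway components, adrenergic neuroblastoma regulators, mesenchymal neuroblastoma markers, sympathetic neuron differentiation, p53 targets, the interferon response, the integrated stress response, cholesterol synthesis, Schwann cell and melanocyte markers, fibroblast and endothelial markers, blood cell markers and replication-dependent histones. Some lists share members, so their tests are not independent. AMOTL2, JUB, LATS2 and PTPN14 are both YAP/TAZ-TEAD targets and Hippo components. TYMS is in the DNA replication and nucleotide synthesis lists, and SESN2 in the p53 and stress response lists. Correlations of fold changes were taken across genes, which are not independent replicates. For the shared controls, 50 data sets of unchanged groups were simulated from the fitted spread, and the labels were set against separate controls in 6 ways, an addition made after the data were seen.

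The planned test of peaks in windows around transcription starts needs hg19 gene coordinates, which were not used here, and the plan was then to describe the peaks only. The lists were also tested between the knockdown labels, a test added after the data were seen. As another such addition, a gene was counted as having a peak when the authors list one of its RefSeq transcripts as overlapping or proximal. Transcripts were named through a table of the GRCh38 assembly, used for names and gene order alone, and 13870 of 14397 accessions (96.3%) matched. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg over 6 tests. Interval estimates of odds ratios are at 95%.

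The analysis was tested on simulated reads in which 66 or 67 genes were changed at each size. For 3 against 3 libraries of the first set (15078 genes), 62.7%, 95.5% and 100% of changes of 0.3, 0.6 and 1 on the log2 scale were recovered, with 1.71% false calls. For 2 against 3 of the second set (14127 genes), these were 23.9%, 89.6% and 98.5%, with 4.08% false calls. Only genes above a minimum mean read count were changed, and far fewer than were called in the data. All genes of a set had the same dispersion (0.002 and 0.00433), and no library stood apart. Real recovery may therefore be lower, and real false calls more frequent. Alternatives were median-of-ratios size factors, no filter, a filter at a CPM of 1, voom weights on the recovered reads, each library left out, a replicate block, and only the compared groups in the fit. A pseudocount of 2 reads, total reads as library size and the peak assignments were added after seeing the data. The planned DESeq2 alternative was not run, as it needs deposited counts. Recovered reads were between 16558866 and 20763734 per library in the first set and between 11504940 and 14534045 in the second. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.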

Results

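Expression was profiled by RNA-seq in the neuroblastoma line SK-N-BE2 after lentiviral short hairpin RNA against TEAD4, MYCN or WWTR1. TEAD4 is a DNA-binding factor of the Hippo pathway, WWTR1 (TAZ) is a coactivator of TEAD factors, and MYCN is the MYC family oncogene of neuroblastoma. The study design names a positive feedback loop between TEAD4 and MYCN. A first set of 9 libraries held 3 with control hairpins, 3 labelled MYCN KD and 3 labelled TEAD4 KD, with 16558866 to 20763734 recovered reads each over 18179 genes. A second set of 5 libraries held 3 with empty vector and 2 labelled WWTR1 KD, with 11504940 to 14534045 reads over 16619 genes. A TEAD4 ChIP-seq peak list came from 1 library without a replicate. Replicate libraries differed by more than sampling noise, with a mean chi-square per gene of 1.32 to 10.6 where sampling alone gives 1. Control replicate 3 of the first set stood apart from replicates 1 and 2 (10.6 and 8.35, against 1.79 between those).

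The targeted genes were examined first, as a check of the labels. TEAD4 mRNA was at 21.6 ± 1.8 CPM (SD, n = 3) with control hairpins, at 2.7 ± 0.4 CPM (n = 3) in the libraries labelled MYCN KD and at 13.5 ± 0.2 CPM (n = 3) in those labelled TEAD4 KD. Every library labelled MYCN KD (2.2, 2.8 and 3.0 CPM) lay below every library labelled TEAD4 KD (13.3, 13.4 and 13.7 CPM). MYCN mRNA was at 3419.6 ± 84.2 CPM in the controls, 2938.9 ± 69.7 CPM with the MYCN KD label and 2740.0 ± 44.2 CPM with the TEAD4 KD label. The level of TEAD4 thus goes against the titles and follows the treatment protocols, which name TEAD4 hairpins for the libraries labelled MYCN KD. WWTR1 was at 17.8 ± 2.2, 17.2 ± 0.4 and 26.4 ± 1.5 CPM in the same 3 groups. In the second set WWTR1 went from 35.7 ± 0.2 CPM (n = 3) with empty vector to 8.4 ± 1.1 CPM (n = 2) with the WWTR1 KD label, as its title says. TEAD4 there was at 20.9 ± 1.6 and 20.0 ± 2.3 CPM, and MYCN at 2404.8 ± 138.2 and 2787.4 ± 63.5 CPM.

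**Figure D1:**
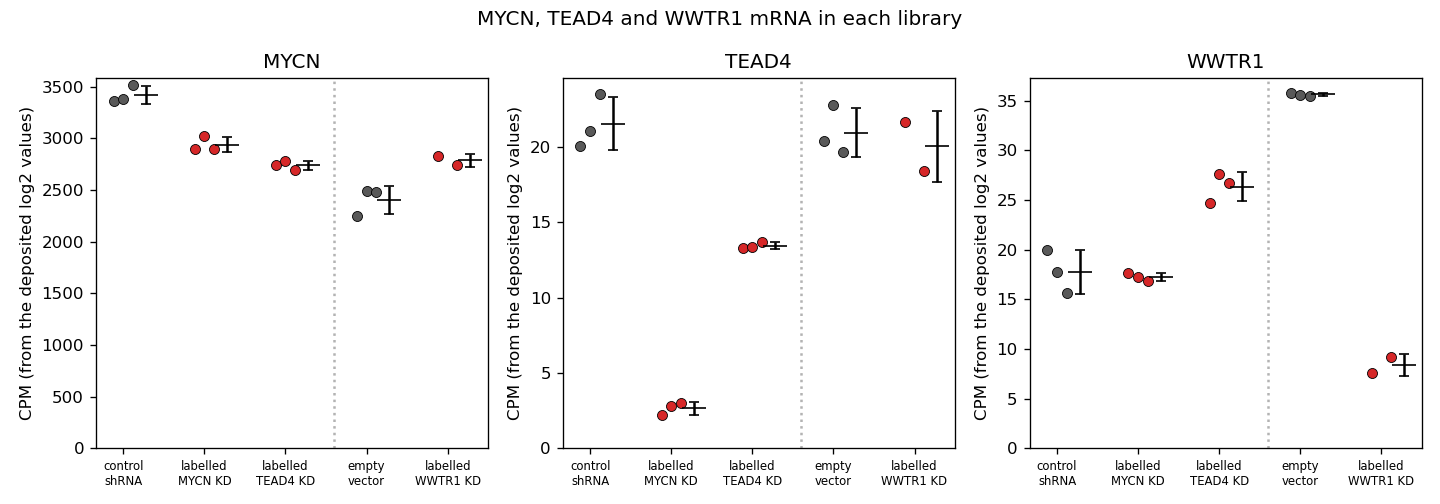
CPM of MYCN, TEAD4 and WWTR1 (y axis, from the deposited log2 values, starting at 0) in each library by group (x axis); points are libraries, bars are means with SD, and the dotted line parts the sets, which were not compared. TEAD4 sits at 2.2 to 3.0 CPM in the libraries labelled MYCN KD and at 13.3 to 13.7 CPM in those labelled TEAD4 KD.

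The question for the libraries labelled MYCN KD, in which TEAD4 and not MYCN had the larger fall, was which genes differed from the control hairpins. Genes of cell division and DNA synthesis fell together. E2F1, a driver of S phase entry, was 5.13-fold lower (log2 fold change -2.36 ± 0.07 SE, n = 3 and 3, limma adjusted p = 9.53e-12), and E2F8 was 4.37-fold lower. POLE4, a subunit of DNA polymerase epsilon, was 7.04-fold lower, HSPBP1, a regulator of HSP70, 5.43-fold lower, and LOXL2, a collagen cross-linking oxidase, 4.78-fold lower. Among the highest with a mean log2 CPM of at least 3 were COX7C, a cytochrome c oxidase subunit (3.09-fold), DDIT4, an inhibitor of mTORC1 (2.99-fold), the nucleotide sugar transporter SLC35D2 (2.97-fold) and the antiproliferative gene BTG2 (2.82-fold). TEAD4 itself was 8.13-fold lower (-3.02 ± 0.11, adjusted p = 9.49e-11), MYCN 1.16-fold lower (-0.22 ± 0.04, adjusted p = 0.000254), and WWTR1 did not pass (-0.04 ± 0.09, adjusted p = 0.746).

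By list, all 28 mitosis genes fell (median log2 fold change -0.94), among them the mitotic regulators MYBL2 (-1.73 ± 0.06) and FOXM1 (-1.21 ± 0.04). Of the 30 DNA replication genes 29 fell and 1 rose (median -1.14), with RRM2, the ribonucleotide reductase subunit, at -1.60 ± 0.04. Both lists passed camera (adjusted p = 2.1e-26 and 8.5e-27) and held with an estimated correlation (adjusted p = 0.0038 and 0.0015). Cholesterol synthesis genes followed, with 13 of 20 down and 1 up (median -0.27, adjusted p = 0.00016, and 0.034 with an estimated correlation). Of 24 nucleotide and one-carbon synthesis genes 11 fell and 3 rose, with TYMS, thymidylate synthase, at -1.66 ± 0.08 and MTHFD1 at -0.57 ± 0.04. That list passed (adjusted p = 0.0037), but not with an estimated correlation (adjusted p = 0.18). Of 22 p53 targets 10 rose and 3 fell, among them BTG2 and TP53INP1 (1.00 ± 0.06), with adjusted p = 0.016, and adjusted p = 0.089 with an estimated correlation. Counts adjusted over the list alone were the same for mitosis, DNA replication, nucleotide synthesis and p53 targets, and 15 down and 2 up for cholesterol synthesis.

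The growth lists tied to MYC did not pass for this label. Ribosome biogenesis genes numbered 5 up and 4 down of 28 (adjusted p = 0.95), with NPM1 at 0.27 ± 0.04 and MRTO4 at -0.50 ± 0.05. MYC family targets numbered 7 up and 7 down of 26 (adjusted p = 0.75), with PTMA at -0.79 ± 0.04 and LDHA at -0.67 ± 0.05. YAP/TAZ-TEAD targets went both ways, 8 up and 7 down of 24 (adjusted p = 0.42): ANKRD1 rose by 1.42 ± 0.11 and NT5E fell (-1.07 ± 0.07). CTGF (0.39 ± 0.09, limma adjusted p = 0.0032) and CYR61 (0.53 ± 0.06, limma adjusted p = 4.8e-06) also rose, although TEAD4 was lowest under this label. Hippo pathway components, a list that holds TEAD4, counted 6 up and 10 down of 25, with TEAD1 at -0.88 ± 0.07. Sympathetic neuron genes counted 13 up and 11 down of 30, and the growth cone protein GAP43 (-2.04 ± 0.05) and the receptor RET (-0.84 ± 0.04) were among those that fell. Adrenergic regulators counted 4 up and 9 down of 20 (HAND1 -0.85 ± 0.06, SOX11 -0.47 ± 0.04), and mesenchymal markers 7 up and 2 down of 27 (VIM 0.28 ± 0.04, NOTCH2 -0.85 ± 0.07). The integrated stress response had 7 up and 5 down of 20 (DDIT4, and SESN2 at 1.42 ± 0.10), and the interferon response 2 up and 3 down of 20 (OAS3 -1.40 ± 0.07, IFIT2 -0.64 ± 0.12). Histones had 4 up of 7 (HIST2H2BE 1.07 ± 0.09, HIST1H2BD 0.41 ± 0.11). Markers of other cells did not move as groups: fibroblast and endothelial 4 up and 2 down of 9 (COL3A1 0.36 ± 0.05, LUM -0.98 ± 0.05), Schwann cell and melanocyte 1 up and 3 down of 8 (L1CAM -0.29 ± 0.05, MITF -1.04 ± 0.20), and 0 of 3 tested blood cell markers passed. Over the list alone the counts were 9 up and 7 down for YAP/TAZ-TEAD targets, 14 and 12 for sympathetic neuron genes, 5 and 9 for adrenergic regulators, and 5 and 2 for fibroblast and endothelial markers. Median and mean differed in sign for sympathetic neuron genes (0.09 and -0.07) and fibroblast and endothelial markers (0.16 and -0.01). Across all genes 6564 of 15078 passed limma, 3222 up and 3342 down, of which 170 rose and 352 fell at least 2-fold. With total reads as library size the larger direction turned, to 3736 up (55.5%) and 2991 down. EIF3CL, the highest by fold among called genes with a mean log2 CPM of at least 3 and no overlap between groups (3.98-fold, SE 0.71 on the log2 scale), has a near-identical copy, EIF3C, and is uncertain: without control replicate 2 its log2 fold change was 0.90, and without any one knockdown replicate its call was lost (adjusted p = 0.0599 to 0.114).

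**Figure D2:**
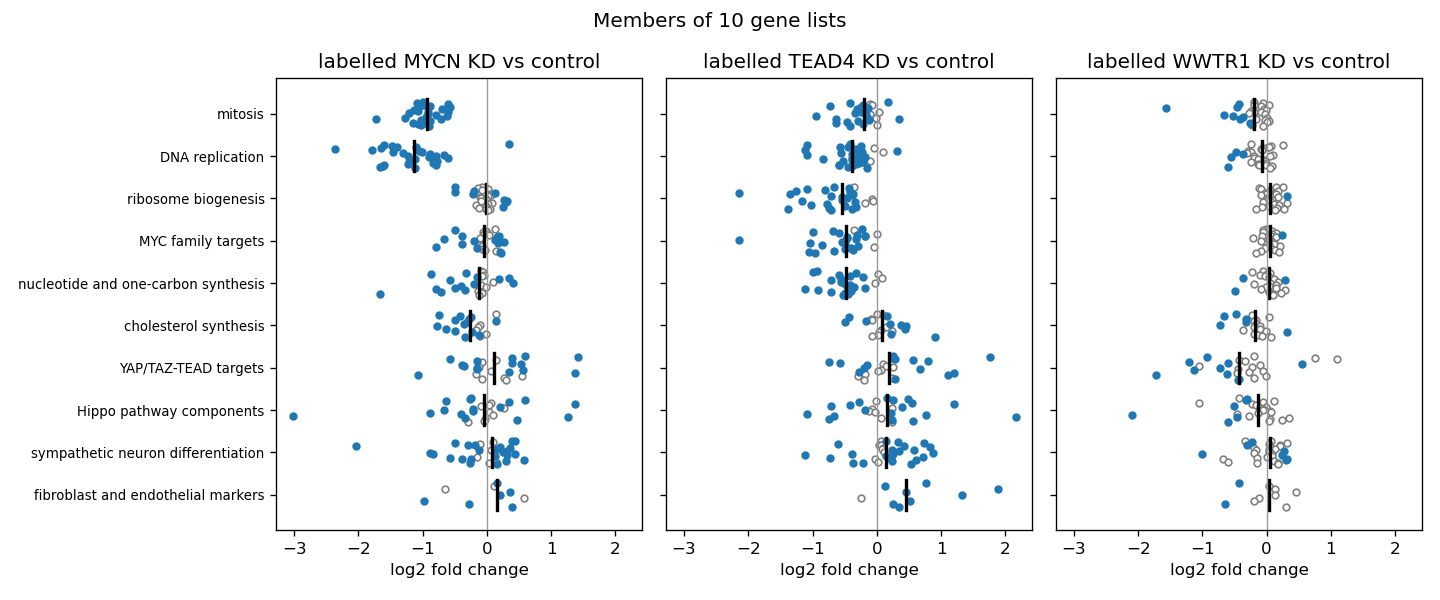
Log2 fold change against the control (x axis) of each tested member of 10 gene lists (y axis) in the 3 comparisons; filled points passed an adjusted p of 0.05, open points did not, and vertical bars are medians. The medians of mitosis and DNA replication are -0.94 and -1.14 with the MYCN KD label, and those of ribosome biogenesis and MYC family targets -0.54 and -0.48 with the TEAD4 KD label.

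For the TEAD4 KD label, whose protocol names MYCN hairpins and where TEAD4 fell less than under the other label, genes that fell included ribosome and nucleotide synthesis genes. NCL, the nucleolar protein nucleolin, was 4.41-fold lower (log2 fold change -2.14 ± 0.04 SE, n = 3 and 3, limma adjusted p = 3.18e-14), and WDR12, a ribosome assembly factor, fell as well (-1.38 ± 0.04). With a mean log2 CPM of at least 3 and no overlap between groups, the lowest genes were the actin bundler FSCN1 (10.8-fold lower), the 14-3-3 protein YWHAE (8.26-fold), the ferritin heavy chain FTH1 (7.09-fold), the myosin light chain MYL12B (6.67-fold) and METTL9 (5.59-fold). The highest under the same limits were TULP3, a cilium trafficking gene (4.58-fold), KIAA0125 (3.87-fold), PLD5 (3.51-fold), the YAP/TAZ target ANKRD1 (3.38-fold) and the clock gene ARNTL (3.23-fold). MYCN was 1.25-fold lower (-0.32 ± 0.04, adjusted p = 5.24e-06), TEAD4 1.59-fold lower (-0.67 ± 0.11, adjusted p = 0.000156) and WWTR1 1.49-fold higher (adjusted p = 6.57e-05). The falls of MYCN and TEAD4 were smaller than those of the lowest genes. Which changes in the first set follow from loss of a target, and which from other effects of the hairpins, was not tested.

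Ribosome biogenesis genes fell in 24 of 28 cases and rose in 0 (median -0.54, camera adjusted p = 5e-13, and 0.024 with an estimated correlation). MYC family targets, which share members with that list, fell in 23 of 26 (median -0.48, adjusted p = 2.7e-11, and adjusted p = 0.066 with an estimated correlation), including the mitochondrial channel VDAC1 (-0.96 ± 0.04). Nucleotide and one-carbon synthesis fell in 21 of 24 (median -0.48, adjusted p = 3e-09, and 0.024 estimated), with CAD, the first enzyme of pyrimidine synthesis, at -0.99 ± 0.04 and ATIC at -0.93 ± 0.04. DNA replication fell in 26 of 30 and rose in 1 (median -0.38, adjusted p = 5e-08, and 0.024 estimated), with E2F2 at -1.11 ± 0.06 and MCM3 at -1.09 ± 0.04. Mitosis had 20 down and 2 up of 28 (median -0.21, adjusted p = 0.00016, and adjusted p = 0.098 with an estimated correlation), with KIF23 at -0.95 ± 0.05 and CCNA2 at -0.73 ± 0.05. Fibroblast and endothelial markers rose in 8 of 9 (median 0.46, adjusted p = 0.00036, and 0.031 estimated), with the matrix protein DCN at 1.31 ± 0.05 and ACTA2 at 0.76 ± 0.06. Sympathetic neuron genes had 16 up and 6 down of 30 (adjusted p = 0.012, and adjusted p = 0.083 with an estimated correlation), with STMN2 at 0.61 ± 0.04 and SCG2 at -1.11 ± 0.04. Counts adjusted over the list alone were the same for these lists, except 24 of 26 for MYC family targets.

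Lists that did not pass for this label were mixed. YAP/TAZ-TEAD targets had 10 up and 5 down of 24 (adjusted p = 0.072, 0.033 without control replicate 1 and 0.046 without knockdown replicate 2; NT5E at 1.11 ± 0.07), and Hippo components 11 up and 7 down of 25 (TEAD3 0.77 ± 0.08, TEAD2 -1.09 ± 0.07). The integrated stress response had 2 up and 10 down of 20 (PSAT1 -0.92 ± 0.05, SLC7A5 -0.70 ± 0.04), and cholesterol synthesis 7 up and 3 down of 20 (HMGCS1 -0.49 ± 0.05). Adrenergic regulators had 5 up and 6 down of 20 (SOX11 -0.69 ± 0.04), mesenchymal markers 10 up and 3 down of 27 (SPARC 0.45 ± 0.05, CBFB -1.59 ± 0.07), and p53 targets 10 up and 4 down of 22 (CCNG1 0.61 ± 0.05, TNFRSF10B -1.56 ± 0.08). Histones had 3 up of 7 (adjusted p = 0.054, and 0.041, 0.045 and 0.049 without control replicate 3, knockdown replicate 2 or knockdown replicate 3; HIST1H2BD 0.95 ± 0.11, HIST2H2BE 0.91 ± 0.09), the interferon response 4 up and 4 down of 20 (IFIT5 -0.28 ± 0.06, OAS3 -0.67 ± 0.07), and Schwann cell and melanocyte markers 2 up and 1 down of 8 (PMP22 0.37 ± 0.05, L1CAM 0.34 ± 0.05). Over the list alone the counts were 3 up and 10 down for the stress response, 6 and 6 for adrenergic regulators, and 10 and 5 for p53 targets, and the interferon list had a median of 0.07 and a mean of -0.01. Of 3 blood cell markers 1 passed, PTPRC, at a mean log2 CPM of -0.29 after knockdown (adjusted p = 0.0489, lost without control replicate 2 or 3 or knockdown replicate 2 or 3, at 0.0883 to 0.207). In all 7847 of 15078 genes passed limma, 3787 up and 4060 down, with 248 rising and 399 falling at least 2-fold. Here too total reads as library size turned the larger direction, to 4432 up (55.5%) and 3550 down. Without control replicate 3, 7915 genes passed here and 6830 passed for the MYCN KD label.

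Set directly against each other, the labels differed in 8777 of 15078 genes (limma), of which 4371 were higher and 4406 lower with the TEAD4 KD label. The larger direction turned with total reads as library size (4513 higher, 4255 lower) and with median-of-ratios size factors (4403 and 4369). LOXL2 (5.95-fold), GAP43 (5.55-fold) and HSPBP1 (5.17-fold) were the highest there among genes with a mean log2 CPM of at least 3 and no overlap, and FSCN1 (9.90-fold), YWHAE (9.09-fold) and the cell cycle factor E2F5 (7.35-fold) the lowest. TEAD4 was 5.09-fold higher with the TEAD4 KD label (log2 difference 2.35 ± 0.11 SE, n = 3 and 3, adjusted p = 3.49e-10), against its title. WWTR1 was 1.53-fold higher (adjusted p = 2.62e-05). MYCN was 1.07-fold lower (-0.10 ± 0.04, adjusted p = 0.03), a call that ended when any one of the 6 libraries was left out (adjusted p = 0.0533 to 0.109) or without the expression filter (adjusted p = 0.0622). Mitosis was higher in 27 of 28 genes and DNA replication in 28 of 30 with the TEAD4 KD label (camera adjusted p = 3.8e-13 and 6.2e-12, and 0.023 and 0.016 with an estimated correlation). Ribosome biogenesis was lower in 23 of 28 (adjusted p = 1.1e-10, and 0.04 estimated). MYC family targets were lower in 20 of 26 and higher in 3 (adjusted p = 2.9e-06, and adjusted p = 0.14 with an estimated correlation). Of the other lists, cholesterol synthesis was higher in 15 and lower in 2 of 20 (adjusted p = 0.0012, and 0.055 estimated), and nucleotide synthesis higher in 3 and lower in 17 of 24 (adjusted p = 0.0012, and 0.12 estimated). The stress response was higher in 2 and lower in 12 of 20 (adjusted p = 0.0094, and 0.14 estimated), and fibroblast and endothelial markers higher in 5 of 9 (adjusted p = 0.019, and 0.12 estimated). YAP/TAZ-TEAD targets did not differ as a list, with 9 higher and 9 lower of 24 (median -0.03, camera adjusted p = 0.71, and 0.79 estimated).

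The calls that these labels shared were counted, which does not by itself test the proposed loop, in which TEAD4 and MYCN would regulate each other. Both labels called 1268 genes up and 1301 genes down, where independent lists would share 809.2 and 899.9, and 1445 genes went opposite ways, where independence gives 1707. Fold changes correlated across 15078 genes at r = 0.222 (Spearman 0.217). As the controls are shared, unchanged groups simulated 50 times gave r of 0.462 to 0.532 and 0 shared calls. These groups held no changed genes, so that 0 does not show how many of the shared calls come from the controls. The covariance was 0.0443 against 0.0117 simulated, a difference of 0.0326. When each label was instead given separate controls, 1 for one and 2 for the other in all 6 ways, r fell to between 0.104 and 0.147 and the covariance to between 0.0235 and 0.0315. Genes called up and down with both labels stayed above independence in each of the 6. As a ratio to independence they were lowest where the TEAD4 KD label had control replicate 3 alone (1050 against 789.8 and 1138 against 898.9, r = 0.104). Genes called in opposite directions were above independence in that split (1747 against 1685.2), near it where the MYCN KD label had control replicate 1 alone (1114 against 1118.8), and below it in the other 4. As 3 controls cannot give 2 to each label, these values rest on a single control for one label, and part of the excess with all 3 shared may come from the controls.

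With the WWTR1 KD label, 9 of 24 YAP/TAZ-TEAD targets fell, 1 rose and 14 did not pass. As a list they had adjusted p = 3e-07, and adjusted p = 0.2 with an estimated correlation. CTGF, the standard reporter of YAP/TAZ activity, was 3.29-fold lower (log2 fold change -1.72 ± 0.15 SE, n = 2 and 3, limma adjusted p = 9.15e-07), CRIM1 was 2.18-fold lower, and CYR61, chosen after its values were seen, had -0.93 ± 0.10 (adjusted p = 5.5e-06). Both CTGF and CYR61 had risen with the MYCN KD label of the first set. With the WWTR1 KD label FOXM1 was 2.96-fold lower (-1.57 ± 0.10, adjusted p = 2.13e-08), and other genes that fell were RAB8B, a membrane traffic GTPase (2.79-fold), and the kinetochore gene SPC24 (2.73-fold). Among called genes with a mean log2 CPM of at least 3 and no overlap, the highest were TULP3 (2.54-fold), the phosphatase DUSP5 (2.02-fold), VMA21 (2.00-fold), KIAA1467 (1.99-fold) and CPEB2 (1.96-fold). WWTR1 was 4.27-fold lower (-2.10 ± 0.13, adjusted p = 2.13e-08) and TEAD4 did not pass (-0.06 ± 0.13, adjusted p = 0.842). MYCN was 1.16-fold higher (0.21 ± 0.06, adjusted p = 0.0252), which was lost without control replicate 3 (adjusted p = 0.118), without control replicate 5 (adjusted p = 0.122) or without the filter (adjusted p = 0.0965).

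By list, tested with camera, YAP/TAZ-TEAD targets had a median of -0.43, with 14 down and 2 up adjusted over the list alone. Mitosis had 9 of 28 down (15 over the list alone; median -0.19, adjusted p = 3e-07, and adjusted p = 0.26 with an estimated correlation), with TOP2A at -0.67 ± 0.07. Hippo components, which include WWTR1 and share members with YAP/TAZ-TEAD targets, had 6 of 25 down (9 over the list alone). Their camera adjusted p was 0.0013, and 0.23 estimated, with FRMD6 at -0.50 ± 0.07. Cholesterol synthesis had 5 down and 1 up of 20 (8 down and 1 up over the list alone; adjusted p = 0.00041, and 0.26 estimated), among them SREBF2, its transcription factor (-0.72 ± 0.08). DNA replication had 4 of 30 down (7 over the list alone; adjusted p = 0.018, and 0.42 estimated; CCNE2 -0.60 ± 0.10, RRM2 -0.56 ± 0.07), histones 1 of 8 down (HIST1H2BK -1.32 ± 0.18; adjusted p = 0.016, and 0.26 estimated), and ribosome biogenesis 1 of 28 up (POLR1B 0.32 ± 0.08; adjusted p = 0.04, and 0.34 estimated). With an estimated correlation none of these 7 lists held. For YAP/TAZ-TEAD targets, Hippo components and histones the estimate itself was 0.011, -0.026 and -0.031, near or below the preset 0.01. Correlation between genes thus did not end these calls, and the fewer degrees of freedom of that setting did. DNA replication also failed without knockdown replicate 1 (adjusted p = 0.11), histones without control replicate 3 or 5 or knockdown replicate 1 (0.063, 0.056 and 0.086), and ribosome biogenesis without control replicate 3 or either knockdown replicate (0.11, 0.067 and 0.13). Lists that did not pass included MYC family targets, 1 up of 26 (0 over the list alone; APEX1 0.24 ± 0.07; adjusted p = 0.13, and 0.042 without control replicate 4), and p53 targets, 5 down of 22 (TP53INP1 -0.89 ± 0.13, MDM2 -0.62 ± 0.09). Sympathetic neuron genes had 4 up and 3 down of 30 (NEFM 0.31 ± 0.07, NEFH 0.501 times the control), adrenergic regulators 3 down of 20 (GATA2 -0.37 ± 0.07, PHOX2A -0.35 ± 0.09), and mesenchymal markers 1 up and 3 down of 28 (TWIST1 0.44 ± 0.07, THY1 -0.58 ± 0.10). Nucleotide synthesis had 1 up and 2 down of 24 (MTHFD2 0.28 ± 0.07, TYMS -0.37 ± 0.09), and fibroblast and endothelial markers 2 down of 9 (PDGFRB -0.64 ± 0.08, ACTA2 -0.43 ± 0.09). Adjusted over the list alone the counts were 6 up and 7 down for sympathetic neuron genes, 4 down for adrenergic regulators, 3 up and 2 down for nucleotide synthesis, and 1 up and 5 down for p53 targets. Several single calls depended on a library: POLR1B and MTHFD2 were lost without control replicate 4 (adjusted p = 0.123 and 0.0563) or 5 (0.128 and 0.122), TYMS without control replicate 3 (0.0521) or 4 (0.0593), and NEFM without control replicate 4 (0.0535). APEX1 was lost without any one of control replicates 3, 4 and 5 (0.102, 0.116 and 0.131) or without the filter (0.0505), and PHOX2A without control replicate 4 or 5, knockdown replicate 2 or the filter (0.145, 0.118, 0.105 and 0.0688). Median and mean differed in sign for adrenergic regulators (0.01 and -0.02), sympathetic neuron genes (0.05 and -0.04), the interferon response (0.03 and -0.06) and fibroblast and endothelial markers (0.04 and -0.04). For the interferon response, the integrated stress response, Schwann cell and melanocyte markers and blood cell markers, 0 of 19, 0 of 20, 0 of 10 and 0 of 4 tested members passed.

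In all 1128 of 14127 genes passed limma in the second set, 353 up (31.3%) and 775 down, with 12 rising and 52 falling at least 2-fold. The controls of this set held empty vector and no control hairpin, so an effect of hairpin expression cannot be told apart from loss of WWTR1. With total reads as library size 1156 passed, 485 up (42%) and 671 down. The count rests on few libraries: it was 800 without control replicate 3, 618 without control replicate 4, 545 without control replicate 5 and 1849 without knockdown replicate 1 (1550 without replicate 2). Across 13914 genes tested in both sets, fold changes with the WWTR1 KD label correlated at r = 0.067 with those under the MYCN KD label (Spearman 0.078; r = 0.118 among genes with a mean log2 CPM of at least 3) and at r = -0.007 with those under the TEAD4 KD label (Spearman -0.001). Genes falling with both the WWTR1 and MYCN KD labels numbered 280, against 182.5 for independent lists, and genes rising with both 143 against 77.2. For the WWTR1 and TEAD4 KD labels the numbers were 252 against 220.5 and 166 against 91.6, and genes called in opposite directions also exceeded independence, at 355 against 301.6. For the WWTR1 and MYCN KD labels 217 genes were called in opposite directions, against 252.8.

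The TEAD4 ChIP-seq list, in hg19, held 34320 peaks with a median width of 1019 bp and a median fold enrichment, as the authors give it, of 13.9 (quartiles 9.9 and 21.6). Of these peaks 52.0% overlapped a RefSeq gene, 27.1% had a gene listed as proximal and 34.4% had neither. WWTR1 was overlapped by 1 peak, on chromosome 3 from 149418015 to 149419111 (fold enrichment 17.9). No peak overlapped or was proximal to MYCN, TEAD4 or YAP1, although MYCN was the closest gene of 2 peaks, on chromosome 2 from 15948906 to 15950067 (10.6) and from 15982507 to 15983778 (11.02). Of 25 YAP/TAZ-TEAD targets 17 had an overlapping or proximal peak, where 8298 of 16724 genes with a RefSeq transcript and an expression row had one. The difference was not tested, and gene length was not taken into account: RBMS3, DLC1 and ASAP1 had 44, 30 and 26 overlapping peaks. Targets with a peak included GADD45A (chromosome 1, 68159266 to 68161062, fold enrichment 59.0), JUB (chromosome 14, 23481937 to 23482911, 34.4) and ANKRD1 (chromosome 10, 92724720 to 92725925, 10.6). CYR61 had a proximal peak (chromosome 1, 86038409 to 86039733, 8.19), and CTGF had none listed. Whether peaks lie in exons or introns was not analysed here.

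Genes called in the knockdowns were set against genes not called for an overlapping or proximal peak. With the MYCN KD label, whose TEAD4 level was lowest, 57.0% of 3237 genes called down had a peak against 49.9% of 7718 not called (odds ratio 1.33, interval 1.22 to 1.45, Fisher adjusted p = 3.77e-11), while genes called up did not differ (51.4%, odds ratio 1.06, adjusted p = 0.177). With the TEAD4 KD label it was the genes called up that had more peaks, 59.2% of 3587 against 47.9% of 6463 (odds ratio 1.58, interval 1.45 to 1.71, adjusted p = 1.22e-26), and 51.8% of those called down (odds ratio 1.17, adjusted p = 0.000172). The WWTR1 KD label gave 63.6% of 763 genes called down and 62.6% of 350 called up against 51.5% of 12178 (odds ratios 1.64 and 1.58, adjusted p = 1.38e-10 and 6.69e-05). Genes are not independent replicates, gene length was not taken into account, and with proximal genes alone the odds ratio of genes called down with the TEAD4 KD label lost its call (1.06, adjusted p = 0.193).

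**Figure D3:**
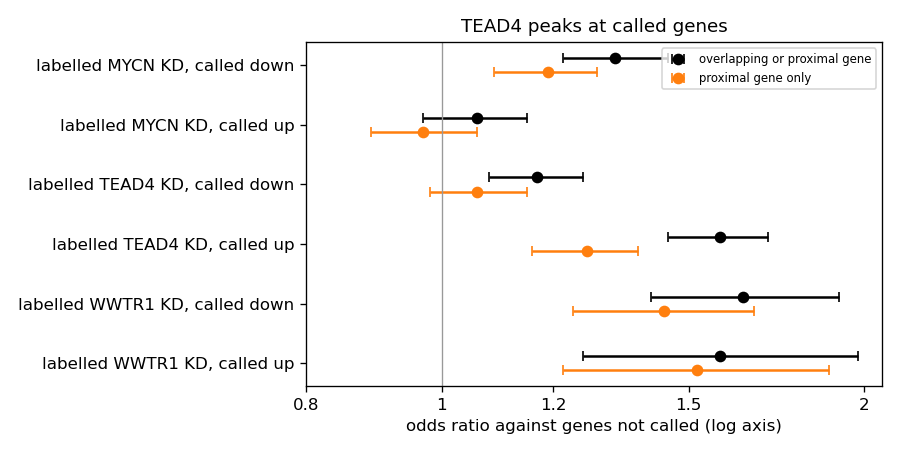
Odds ratio (x axis, log scale) with its 95% interval of an assigned TEAD4 peak among genes called down or up in each comparison (y axis), against genes not called; black, overlapping or proximal genes; orange, proximal genes alone. The odds ratio is 1.33 for genes called down with the MYCN KD label and 1.58 for genes called up with the TEAD4 KD label.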

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

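The peak assignments, the pseudocount of 2 reads and the scaling by total reads were chosen after the data were seen. Counts of called genes stayed within 1.5 times of the reported ones in the first set under all alternatives run. Leaving out each library gave 5449 to 6830 genes with the MYCN KD label (6564), 6843 to 7915 with the TEAD4 KD label (7847) and 7926 to 8243 between the labels (8777). With the WWTR1 KD label it gave 545 to 1849 (1128), and 839 came without the filter. Lists past the threshold numbered 19 over the 3 comparisons and 7 with an estimated correlation, a setting that also lowers the degrees of freedom. Without each library they numbered 5 throughout for the MYCN KD label, 7 to 9 for the TEAD4 KD label and 4 to 8 for the WWTR1 KD label, 4 without knockdown replicate 1. Correlations ranged from 0.216 to 0.262 between the MYCN and TEAD4 KD labels, from 0.048 to 0.076 between the MYCN and WWTR1 KD labels and from -0.023 to 0.013 between the TEAD4 and WWTR1 KD labels when libraries were left out. With a mean log2 CPM of at least 3 the first was 0.161 and the second 0.118, and with separate controls the first was 0.104 to 0.147. The cause was not tested.

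For peaks, the odds ratio of genes called up with the MYCN KD label, not past the threshold, turned to 0.97 with proximal genes, 0.99 with the closest gene and 0.95 by Mantel-Haenszel over expression deciles. That of genes called down with the TEAD4 KD label was 1.06 (adjusted p = 0.193) with proximal genes, 1.08 (adjusted p = 0.112) with the peaks at or above the median enrichment and 1.02 by Mantel-Haenszel. Mantel-Haenszel also gave 1.2 for genes called down with the MYCN KD label, 1.39 for genes called up with the TEAD4 KD label and 1.4 for genes called down with the WWTR1 KD label, nearer to 1 than the reported values (1.34 for genes called up with that label), and by its construction it takes expression into account. Of 132 values of named genes, 130 passed the threshold, 0 reversed and 10 lost their call under some alternative, 7 of them with the WWTR1 KD label.

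The replicate numbers of the first set did not pair the libraries: deviations of same-numbered libraries correlated at -0.18 to 0.06, 0 of 9 pairs over 0.1, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block 6124, 7427 and 8418 genes passed, 2303 calls were shared between the labels (2569 without the block), 13 lists passed (12 without), the correlation was 0.222, and MYCN between the labels had adjusted p = 0.066. The DESeq2 alternative and the windows around transcription starts were not run. Small changes can be missed: simulated recovery of changes of 0.3 on the log2 scale was 62.7% in the first set and 23.9% in the second. That simulation gave all genes of a set the same dispersion and had no outlying library, so it may overstate recovery. The sets differed in group size and spread as well as in depth, and the part of depth was not tested.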

Other observations

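The tests in this part were chosen after the results were seen. Besides the named genes, MYC itself was higher with both labels of the first set, from a mean log2 CPM of 0.05 in the controls, 2.47-fold (SE 0.19 on the log2 scale, limma adjusted p = 7.61e-05) with the MYCN KD label and 2.83-fold (SE 0.19, adjusted p = 1.45e-05) with the TEAD4 KD label. MYC then stood at 1.36 and 1.55 log2 CPM, where MYCN stood at 11.52 and 11.42. In the second set MYC did not pass (-0.77 ± 0.37, adjusted p = 0.245).

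Of 13914 genes tested throughout, 86 rose and 105 fell in all 3 knockdowns, where independence of the second set from the first gives 30.8 and 71.9. Those that fell by the most in their weakest comparison were the receptor tyrosine kinase KIT (-1.02, -1.76 and -0.88 with the MYCN, TEAD4 and WWTR1 KD labels), the uracil glycosylase UNG (-0.74, -1.87 and -1.08) and SOST (-0.69, -1.94 and -0.86). TOP2A (-1.15, -0.63 and -0.67), cyclin CCNE2 (-1.60, -1.09 and -0.60) and RRM2 (-1.60, -0.59 and -0.56) also fell in all 3. Rising genes were led by TULP3, then SAMD15 (1.61, 0.92 and 1.99), the translation regulator CPEB2 (0.87, 0.88 and 0.97) and COX7C (1.63, 1.53 and 0.66). With the WWTR1 KD label KIT, SOST and SAMD15 passed narrowly, with SEs of 0.26, 0.24 and 0.56 (limma adjusted p = 0.0453, 0.0323 and 0.0329). The overlap itself was not tested.

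TEAD4 was lowest in the libraries labelled MYCN KD, and a candidate explanation is that the titles of the 2 knockdown groups were exchanged. If the titles were correct, TEAD4 should not be higher in the libraries labelled TEAD4 KD, and it was, by 2.35 ± 0.11 on the log2 scale. With the TEAD4 KD label against the MYCN KD label, MYC family targets had a median of -0.37 and passed camera (adjusted p = 2.9e-06). They did not pass camera with an estimated correlation (adjusted p = 0.14). Ribosome biogenesis, lower in 23 of 28 genes and higher in 0 (median -0.61), passed in that setting (camera adjusted p = 0.04). MYCN mRNA differed by -0.10 only, a call lost when any one of the 6 libraries was left out (adjusted p = 0.0533 to 0.109), and does not settle it. The list chosen for this question was MYC family targets, with which ribosome biogenesis shares members. YAP/TAZ-TEAD targets did not separate the labels (9 higher and 9 lower of 24, camera adjusted p = 0.71). Mitosis and DNA replication were higher with the TEAD4 KD label in 27 of 28 and 28 of 30 genes. The TEAD4 level argues against correct titles, and with the treatment protocols it goes with an exchange, while the treatment tags follow the titles. MYC family targets go with an exchange too at the preset correlation, and the other lists do not decide it. Protein levels were not analysed here.

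TULP3, a neighbour of TEAD4 in the gene order of the reference, was higher in all 3 knockdowns, by 1.27 ± 0.06, 2.19 ± 0.06 and 1.35 ± 0.11 on the log2 scale. A rise of the whole neighbourhood was argued against by FKBP4, ITFG2, NRIP2, FOXM1 and TSPAN9, whose medians were -0.31, -0.34 and -0.15 (NRIP2 was not tested in the second set), although FKBP4 and TSPAN9 each rose in at least 1 comparison. A response of one size to any targeting hairpin was argued against by the difference of 0.92 ± 0.06 between the TEAD4 and MYCN KD labels. A response of varying size to hairpins, an effect of hairpin sequences on other transcripts, and a response to the loss of each factor remain open and were not tested.

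Each 3 against 3 comparison has 10 splits of its 6 libraries, too few for a share under 0.05. The real split gave 6564, 7847 and 8777 genes for the MYCN KD label, the TEAD4 KD label and the labels against each other, and the highest of the other splits gave 0 in each, so that 1 split of 10 reached the real count. Each other split held libraries of both groups on both sides, so the group difference entered its spread. Low counts there follow from that mixing and do not bear on whether the real grouping arose by chance.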
